A study of Mus musculus with 2 samples.

How the data were processed

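DNase-seq libraries from frontal cortex of female B6CASTF1/J mice were analysed from the processed files the authors deposited. The labels give 1 group of 2 biological replicates with separate biosamples and 1 donor label. One label of both samples carries the mark 3x, whose meaning is not stated, so whether tissue of several animals was pooled is unknown, and the spread between libraries may be partly technical.

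Per the deposited notes of each library, peaks, footprints and FDR cut rates were called from that library's own alignments to mm10, so replicates were not pooled. The aligner, the peak caller, their versions and the filters are not given in the sources used here. The strength of each peak is a signal that, per the deposited notes, is normalized for read depth by the authors, and its scale is not stated. The deposited FDR values (p-value scale) cover stretches of bases, and every stretch listed has an FDR below 0.05. Each library has 2 peak lists. The longer was used throughout and the shorter (53068 peaks in replicate 1 and 36975 in replicate 2) served as the stricter alternative. The thresholds behind the lists are not stated. The footprint files hold 1 constant in the value column, so positions alone were used. Because no counts are given for places without a peak, the planned comparison over the union of peaks was not run, and the planned count-based spread rests on multiples of the smallest signal step, each taken as 1 cut.

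Coordinates were compared with the GRCm38 reference, and 0 peaks or footprints reached past a chromosome end. Annotation came from GENCODE M21. Overlaps were computed with numpy 2.4.6 and bedtools 2.31.1, statistics with scipy 1.17.1, tables with pandas 2.3.3 and sequences with pysam 0.24.0. Peaks were called shared when they overlapped by at least 1 bp. Chance overlap came from 100 circular shifts per chromosome. Strength was compared over merged regions, with the maximum per library. A promoter peak overlapped the 500 bp on either side of any annotated TSS. Linked peaks overlapped no such window and had their midpoint in the gene body plus 10 kb on each side.

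The design, tests, 18 gene lists, 28 consensus sequences, named genes rule and most alternative settings were fixed before the data were examined. The lists cover pan-neuronal, excitatory, inhibitory, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural, activity-regulated, forebrain, posterior and cerebellar, striatal with thalamic and olfactory, liver and gut, blood and lymphoid, muscle and heart, housekeeping, imprinted and sex chromosome genes. Each list's promoter share was placed among 10000 random lists matched on TSS number in 5 bins, and its median linked peaks among 10000 lists matched on gene length in 10 bins, drawn with replacement. Lists above the 95th percentile were counted. That percentile was set after the files were opened and before list results were seen.

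Named genes were, per list, the 2 with the highest mean rank of promoter strength, the 2 with the most linked peaks and, for brain cell types, up to 4 in list order without a promoter peak. Genome-wide they were the 5 genes with the most linked peaks, the 5 with the most per 100 kb among those with at least 20, the 5 strongest shared peaks, the 5 strongest peaks of each library alone, the sex chromosome genes with a promoter peak, and the 5 highest and 5 lowest consensus ratios. A subset is printed. Footprints lying inside a peak were extended by 5 bp on each side and compared with 10 random placements in the same peak outside footprints, with 95% intervals from 200 Poisson-weighted resamples of peaks. HNF1, AP-1 and the neurogenic E-box are named outside the rule, and were chosen after their values were seen. The FDR comparison at unshared peaks and the distances of the strongest of them to the other library's peaks were also chosen after seeing the data.

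The functions were tested on simulated data. Overlap calls equalled those of bedtools for all 5000 simulated intervals, unrelated lists gave a mean fold over chance of 0.992, and 3% of 200 unrelated gene lists passed the 95th percentile. Intervals cover counting error only. With 1 group of 2 libraries no test between groups was possible. Alternatives were the stricter list, equal numbers of strongest peaks, each replicate alone, 50% reciprocal overlap, local shifts, other windows, flanks and TSS sets, other footprint sets and comparison windows, and other strength measures and filters. The alternatives added after seeing the data were the 97.5th percentile, the stricter list for the spread, and peaks outside 50 kb windows dense in one library.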

Results

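DNase-seq was measured in frontal cortex of female B6CASTF1/J mice aged 14 days, an F1 cross of the C57BL/6J and CAST/EiJ strains. DNase I cuts DNA where it is not wrapped in nucleosomes, so that dense cutting marks accessible sites such as promoters and enhancers. Short stretches inside those sites that are protected from cutting are called footprints. The data held 2 libraries, labelled as biological replicates 1 and 2 of 1 group, with separate biosamples and the same donor label. No treatment or second tissue was labelled, so replicate was compared with replicate and the accessible sites were described by gene, region and sequence. The deposited peak strengths were whole multiples of a step of 0.00670 in replicate 1 and 0.00858 in replicate 2 for 100% of peaks, within 0.05 steps. The median peak held 99 steps in replicate 1 and 83 in replicate 2. If 1 step stands for 1 cut, replicate 1 was 1.28 times as deep as replicate 2. The scale of the strength was not stated, so total reads are unknown. Positions refer to the mouse build mm10 (GRCm38).

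Promoters of Rplp0, Tle4, Kdm6a and Jun were strongly accessible in both libraries. Rplp0, which encodes a ribosomal protein, had a promoter peak of strength 12.03 at chromosome 5, 115559281 to 115559520, in replicate 1 and of 8.47 in replicate 2. Tle4, a transcriptional corepressor expressed in deep cortical layers, had a promoter peak of 12.02 in replicate 1 (chromosome 19, 14598261 to 14598500) and 6.56 in replicate 2. Kdm6a, an X-linked histone demethylase, reached 11.9 in replicate 1 (chromosome X, 18162361 to 18162600) and 6.14 in replicate 2. Jun, an AP-1 subunit, reached 8.84 and 5.86 in replicates 1 and 2.

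Replicate 1 had 93641 peaks and replicate 2 had 66196, a ratio of 1.41 and a mean of 79918.5 ± 19406.5 (SD, n = 2). Of these, 59.1% in replicate 1 and 84.4% in replicate 2 overlapped a peak of the other library by at least 1 bp, a mean of 71.7%. Both shares come from one overlap divided by unequal list lengths. Their SD of 17.9 (0.688 with equal numbers of strongest peaks) is therefore not a spread between replicates. The overlap was 56.9 times the mean of 100 circular shifts of one list along each chromosome (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). In the weakest decile, 13.7% of replicate 1 peaks and 50.4% of replicate 2 peaks were shared. In the strongest decile, 99.6% were shared in each library. Promoter peaks were shared more often than others, with 75.1% against 53.1% in replicate 1 and 88.9% against 82.1% in replicate 2. They were also stronger, with medians of 1.19 against 0.576 and 1.07 against 0.626, and strength was not matched in this comparison.

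**Figure D1:**
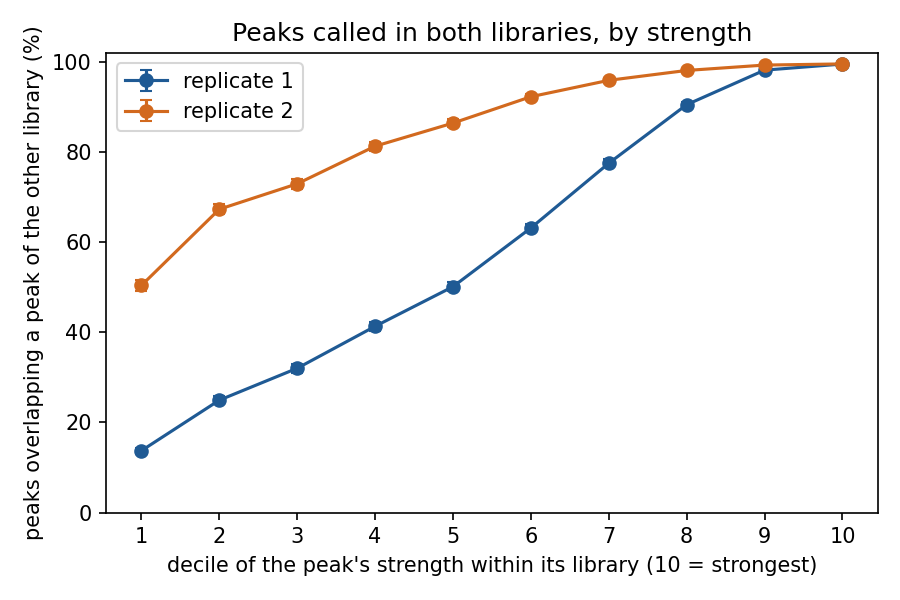
Share of peaks (%) that overlap a peak of the other library, by decile of strength within each library, with Wilson 95% intervals that cover counting error only. The share rises from 13.7% to 99.6% in replicate 1 and from 50.4% to 99.6% in replicate 2.

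The strongest peaks called in one library alone lay at promoters, beside a peak of the other library. In replicate 1 these were near Srd5a1, Mrps28, Dzank1, Ubap2 and Polr2b, with strengths from 5.01 at Polr2b to 6.36 at Srd5a1. In replicate 2 they were near Nsun2, Polr3f, Eif1ad, Mpv17l and Hlcs, with strengths from 3.44 at Hlcs to 4.90 at Nsun2. The genes encode proteins such as an RNA polymerase II subunit (Polr2b) and a mitochondrial ribosomal protein (Mrps28). All 10 had a peak of the other library within 60 bp. Srd5a1 and Nsun2 share one such site on chromosome 13, where replicate 1 had its peak at 69611601 to 69611680 and replicate 2 at 69611741 to 69612040. Dzank1 and Polr3f share another on chromosome 2, so the 10 peaks are not 10 separate sites. Across all peaks called in 1 library, 9.62% in replicate 1 and 31.0% in replicate 2 lay within 200 bp of a peak of the other. Of the 38285 peaks called in replicate 1 alone, 12.2% overlapped bases that the authors' deposited FDR cut rate called in replicate 2, against 1.26% after shifting. The corresponding share for the 10345 replicate 2 peaks was 36.1%, against 1.68% after shifting.

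Across 52787 regions called in both libraries, strengths ranked alike, with a Spearman rho of 0.937 and a Pearson r of 0.944 on the log2 scale. These values are across regions, which are not independent replicates. Replicate 1 was stronger, with a median ratio of 1.25. The ratio was 1.03 in the weakest decile of shared regions and 1.59 in the strongest (95% interval 1.58 to 1.60, 200 resamples of regions). The SD of the log2 ratio was 0.39, against 0.20 from Poisson counting of steps, which leaves out variation between biological replicates. The ratio went with GC content (Spearman rho 0.457 across regions). Promoter regions had a median log2 ratio of 0.52 and other regions 0.22.

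**Figure D2:**
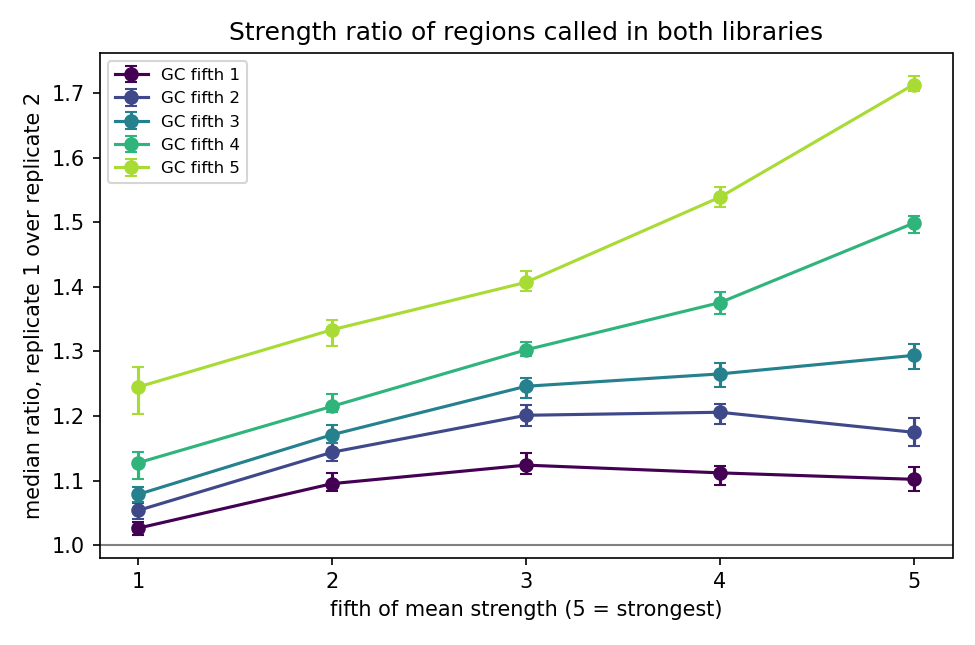
Median ratio of peak strength, replicate 1 over replicate 2, in regions called in both libraries, in 5 equal classes of mean strength and 5 of GC content, with 95% intervals from resampling regions. In the strongest class the ratio rises from 1.102 at the lowest GC content to 1.71 at the highest.

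Accessible sites were concentrated at promoters. Peak midpoints fell within 500 bp of an annotated transcription start site (TSS) for 27.3% of replicate 1 peaks and 33.1% of replicate 2 peaks, a mean of 30.2% ± 4.13 (SD, n = 2), where 3.26% of sequenced bases lie. These shares are 8.37 and 10.2 times those of the genome. Introns held 33.3% ± 2.42 and intergenic sequence 30.5% ± 1.19 of peaks, below their genome shares of 39.8% and 53.2%. Coding exons held 2.42% ± 0.405 against 1.07% of bases. Promoter peaks had a median GC content of 62.9% in each library, and other peaks 51.8% in replicate 1 and 51.5% in replicate 2. The stricter of the authors' lists raised the promoter share to 40.9%.

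Chromosome 11 was the densest in peaks, with 52.8 per Mb in replicate 1 and 38.2 in replicate 2, and chromosome 3 the sparsest autosome, with 30.7 and 21.9. With the stricter list chromosome 1 was the sparsest autosome in replicate 2, at 11.7 per Mb. The X chromosome had 14.3 and 10.8 peaks per Mb, which is 0.389 ± 0.0173 (SD, n = 2) of the autosomal density. Every one of the 10 X-linked genes of the sex chromosome list had a promoter peak in both libraries, though Xist and Tsix had none in replicate 2 with the stricter list. They include Xist, the RNA that silences one X chromosome in females, at a strength of 1.00 in replicate 1 and 0.712 in replicate 2. Ftx, a noncoding gene beside Xist, reached 4.71 and 3.92. None of the 8 Y-linked genes of that list had one in either library. Replicate 1 had 40 peaks on Y and replicate 2 had 28, of which 21 and 22 lay beyond 90 Mb, near the chromosome end that pairs with X.

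Pan-neuronal, activity-regulated and housekeeping genes had open promoters throughout with the longer peak list, and markers of other tissues mostly did not. All 16 pan-neuronal genes had a promoter peak in both libraries, which is the 99.9th percentile of random lists of protein-coding genes with matched numbers of TSSs. The same held for all 20 activity-regulated genes (percentile 100) and all 16 housekeeping genes (percentile 99.8). With the stricter list the pan-neuronal gene Rbfox3 had no promoter peak in replicate 2. Over all 21911 protein-coding genes, 58.8% had a promoter peak in both libraries. Percentiles describe these libraries and are not p-values. By mean rank over both libraries, the strongest promoters among pan-neuronal genes were those of Dlg4, a postsynaptic scaffold, at 3.24 and 2.05 in replicates 1 and 2, and of Gria2, a glutamate receptor subunit, at 3.07 and 2.00. Among activity-regulated genes, Egr1, an immediate early transcription factor, reached 6.23 and 4.75. Because any annotated TSS counts, a promoter peak can lie far inside a gene record or at different TSSs in the 2 libraries. The Dlg4 peaks began at 70029541 and 70029561, in a record that starts at 70016942. The strongest Rbfox3 promoter peaks began at 118911387 in replicate 1 and 118569963 in replicate 2, so they lay at different TSSs.

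Only 1 of 16 muscle and heart genes (percentile 0), 1 of 15 liver and gut genes (percentile 0.02), 3 of 16 blood and lymphoid genes (percentile 0.1) and 3 of 20 posterior and cerebellar genes (percentile 0.07) had a promoter peak in both libraries. The exceptions included Ryr1, a calcium release channel, at 1.31 and 0.789, and Lgr5, a stem cell receptor, at 0.804 and 0.515, which had none in replicate 2 with the stricter list. The Ryr1 peaks began at 29071281 and 29071401, inside its minus-strand record of 29003344 to 29125179. Striatal, thalamic and olfactory genes stood at 6 of 17 (percentile 0.985), with Rgs9, a striatal regulator of G protein signalling, at 3.34 and 2.68. That list rose to 11 of 17 in replicate 1 alone, at percentile 42.1, and the posterior and cerebellar list to 7 of 20, at percentile 4.66, while the liver and muscle lists reached 2 genes each.

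Microglial, vascular and oligodendrocyte markers had few open promoters in both libraries, and astrocyte and oligodendrocyte precursor markers were near the random lists. Microglia had 2 of 15 (percentile 0.01), among them Irf8, a myeloid transcription factor, at 2.17 and 1.60. In replicate 1 alone the list reached 6 of 15, at percentile 3.64. P2ry12, Csf1r, Aif1 and C1qa had none in either library. Endothelial and mural genes had 4 of 16 (percentile 0.125), or 6 of 16 in each library alone, and Cldn5, Tek, Cdh5 and Slco1a4 had none. Oligodendrocyte genes had 5 of 14 (percentile 2.69), with no promoter peak at the myelin genes Mog, Mag and Mobp, and a peak of 1.77 and 1.09 at Olig1, a lineage transcription factor. The oligodendrocyte list reached 8 of 14 in replicate 1 alone, at percentile 27.1. Oligodendrocyte precursor genes stood at 5 of 10 (percentile 31.0), with Pdgfra at 2.10 and 1.28, and astrocyte genes at 10 of 14 (percentile 58.3), with Glul, which encodes glutamine synthetase, at 3.84 and 2.95.

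Excitatory projection neuron genes had promoter peaks at 17 of 19 in replicate 1 and 13 of 19 in replicate 2, and inhibitory interneuron genes at 16 of 19 and 11 of 19. Over all protein-coding genes the shares were 63.8% and 59.2%. In both libraries together the percentiles were 83.9 and 43.0, and in replicate 1 alone 99.7 and 97.8. Fezf2 and Pou3f1 among excitatory genes, and Lhx6, Sst and Vip among inhibitory genes, had no promoter peak in either library. Forebrain transcription factor genes stood at 17 of 20 (percentile 96.96), led in mean rank over both libraries by Id2 at 5.72 and 4.03 and Sox11 at 4.15 and 2.97. Imprinted genes stood at 17 of 20 (percentile 92.5), with the noncoding gene Kcnq1ot1 at 3.98 and 4.36. The forebrain percentile fell to 59.8 with the stricter peak list, to 55.8 without 50 kb windows dense in peaks of one library and to 29.0 with the 5' end of each gene record as its only TSS, and the inhibitory percentile fell to 0.01 with the stricter list.

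Forebrain transcription factor and pan-neuronal genes had the highest medians of linked peaks, which are peaks away from promoters, among the 18 lists. The median forebrain transcription factor gene had 8 linked peaks in replicate 1 and 4.5 in replicate 2, counted over the gene body plus 10 kb on each side (percentile 100 among lists matched on gene length). Pan-neuronal genes had 7.5 and 4 (percentile 100), and activity-regulated genes 4.5 and 2.5 (percentile 100). The median protein-coding gene had 1 in each library. Nfib, a nuclear factor I gene, had 32 and 17 linked peaks (14 and 5 with the stricter list), and Tcf4, an E-protein gene, 27 and 17 (22 and 9). Rbfox3, which encodes the neuronal marker NeuN, had 37 and 17 (25 and 9 with the stricter list), Gria1 29 and 8 (17 and 3), and Pou3f2, a POU factor of upper cortical layers, 16 and 10 (5 and 4).

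Microglial and oligodendrocyte genes had linked peaks in both libraries although few had promoter peaks in both. Microglia genes had a median of 2 linked peaks in each library (percentile 97.9), with 11 and 5 at Cx3cr1, the fractalkine receptor gene (7 and 5 with the stricter list). The Cx3cr1 record spans 119901616 to 120069879 on chromosome 9, so its count may include peaks of neighbouring genes. Oligodendrocyte genes had 2.5 and 2 (percentile 97.1), with 12 and 8 at Mbp, the myelin basic protein gene (9 and 4). Aldh1l1, an astrocyte enzyme gene with no promoter peak, had 11 in each library (6 with the stricter list). Oligodendrocyte precursor genes had 3 and 1.5 (percentile 96.5), and housekeeping genes 2 and 1.5 (percentile 99.7). Excitatory, inhibitory and striatal lists passed the 95th percentile in the mean of both libraries (99.2, 99.8 and 97.9) but not in replicate 2 alone (84.6, 56.2 and 67.4). The oligodendrocyte precursor list stood at 93.6 in replicate 2 alone and the microglia list at 91.6 in replicate 1 alone. With the stricter peak list the excitatory, inhibitory, striatal, oligodendrocyte and microglia lists fell to 68.4, 52.7, 67.3, 90.6 and 91.7, and the imprinted list rose to 99.1.

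The remaining lists stayed below the 95th percentile for linked peaks in the mean of both libraries. Astrocyte genes stood at 94.8 (96.8 in replicate 1 alone), imprinted genes at 94.8 (97.3 in replicate 1 alone), muscle and heart genes at 90.6, blood and lymphoid genes at 87.6, posterior and cerebellar genes at 84.3, liver and gut genes at 61.2 and endothelial and mural genes at 51.8. The sex chromosome list stood at 0.765, or at 20.4 in replicate 2 alone, and its promoter share of 10 of 18 genes at percentile 12.4. Of its genes, 8 are Y-linked and had no promoter peak in these female mice, and all 10 X-linked genes had one. The make-up of the list therefore bears on these percentiles.

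**Figure D3:**
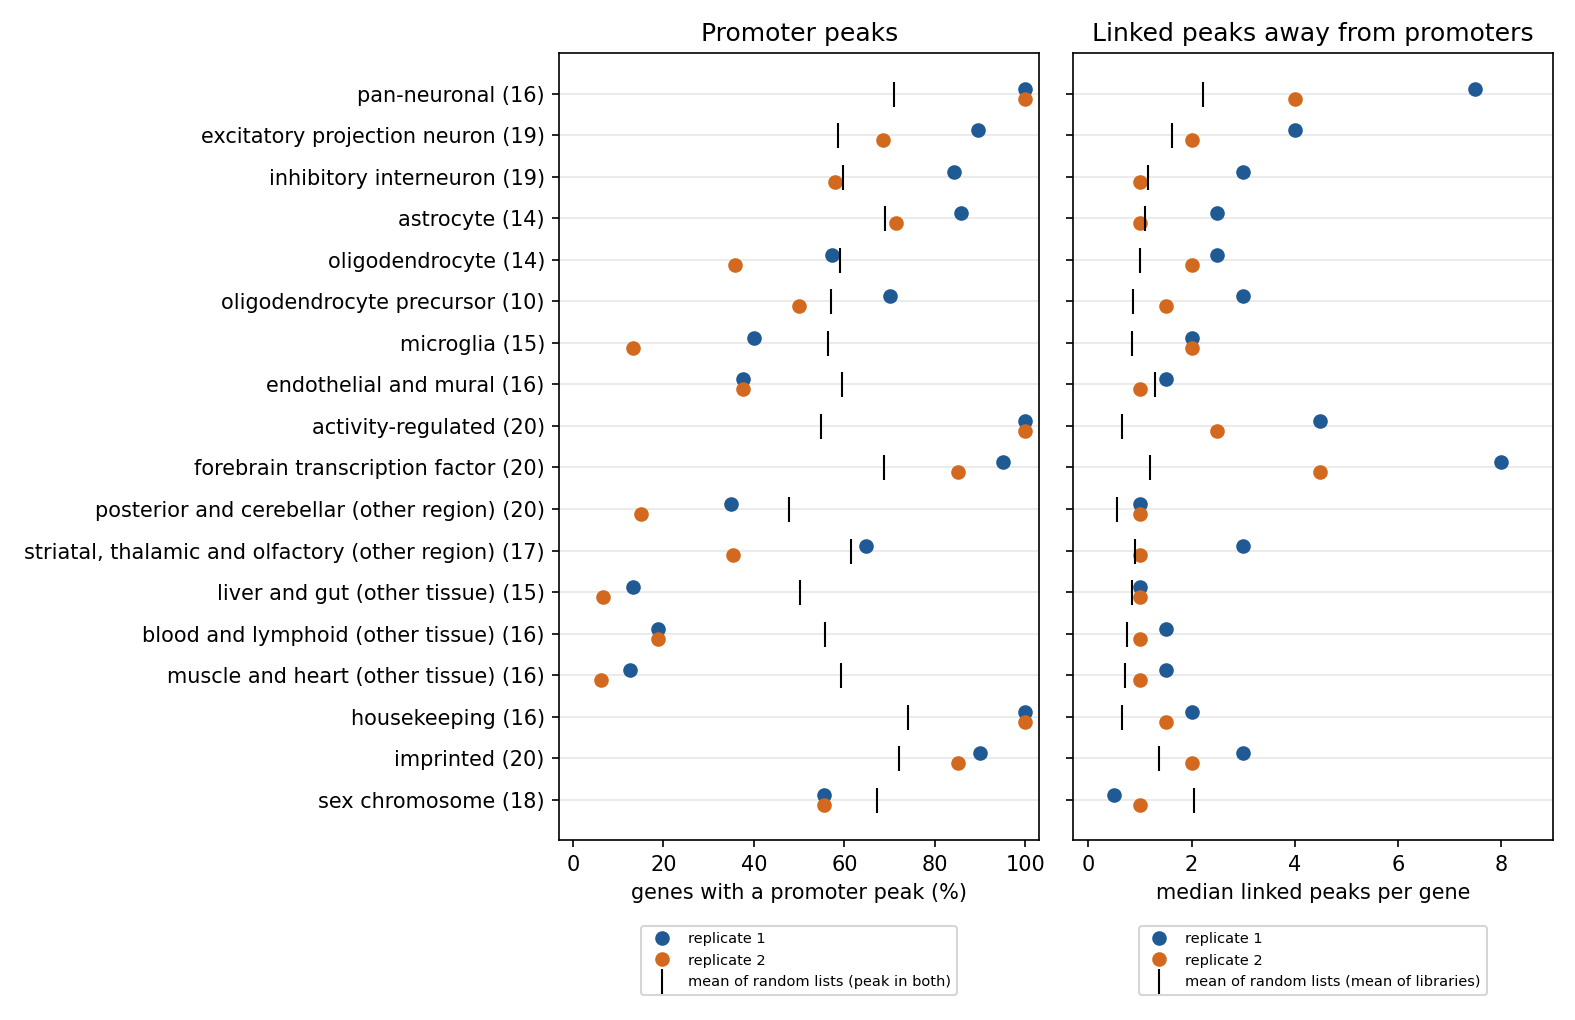
Left, genes of each list with a promoter peak (%) in each library. Right, median number of linked peaks per gene. Circles are single libraries, and gene numbers stand in brackets. Black ticks are means of 10000 matched random lists, for a peak in both libraries (left) and for the mean of both libraries (right). Circles and ticks are therefore not the same measure. Pan-neuronal, activity-regulated and housekeeping genes reach 100% in both libraries, and liver, blood and muscle lists stay below 20%.

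Genome-wide, the protein-coding gene records with the most linked peaks in the mean of both libraries were Gm20388 (272 and 184 in replicates 1 and 2), Fgfr2 (119 and 77), Ptprn2 (81 and 28), Gm37240 (56 and 46) and Asic2 (49 and 44). The Gm20388 record spans 119910841 to 124345722 on chromosome 8 and the Fgfr2 record 130162451 to 133123350 on chromosome 7, so their counts include neighbouring genes. Relative to length, Acap3 on chromosome 4 led, with 25 linked peaks in each library or 70.6 per 100 kb, but with the stricter list it fell to 13 and 12, below the minimum of 20 and, relative to length, behind B4galt5 with 30 and 21. It was followed by B4galt5 (40.3), Nfic (39.0), Sirpa (35.4) and Snap91 (21.5). Snap91, a synaptic vesicle endocytosis gene, had 56 linked peaks in replicate 1 against 2 in replicate 2, and Nfic had 51 against 11.

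The 5 strongest regions called in both libraries did not lie at promoters of protein-coding genes. The first lay at chromosome 17, 39846781 to 39846920, 107 bp from the TSS of Gm42418, a noncoding gene, with strengths of 63.9 and 60.1. The others lay on chromosome 3 (29.2 and 34.2, intergenic), chromosome 9 in the 3' UTR of Lars2 (34.1 and 33.8), chromosome 15 in a 3' UTR 10243 bp from the nearest TSS, that of Cox14 (28.5 and 32.4), and chromosome 6 (28.3 and 25.3, intergenic). No filter for regions prone to mapping errors was applied here, and the filters behind the deposited calls are not given. Mapping artefacts at these sites were therefore not excluded.

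Footprints held the sites of CTCF, nuclear factor I, NRF1, CREB/ATF and EGR far more often than the rest of the same peaks. CTCF, an insulator protein, had its consensus CCASYAGRKGGCR in 2.19% of replicate 1 footprints and 2.81% of replicate 2 footprints, 214 times (95% interval 175 to 280) and 136 times (116 to 166) the share of random windows in the same peaks. The full nuclear factor I site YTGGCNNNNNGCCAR followed, at 63.8 and 38.8 times. Against windows directly beside each footprint, nuclear factor I stood at 131 (95% interval 69.1 to 765) and 120 times (58.8 to 492). CTCF stood there at 136 (104 to 182) and 85.9 times (67.4 to 113), and EGR at 19.3 and 25.1. CTCF was then below nuclear factor I in replicate 2, but their intervals overlapped in each library, so these windows do not settle the order. NRF1 (GCGCMTGCGC) stood at 11.4 and 18.9 times, CREB/ATF (TGACGTCA) at 18.2 and 9.17 times, and EGR (GCGTGGGCG) at 11.7 and 12.5 times. The neurogenic E-box CCATCTGKY was at 3.85 and 3.79 times in all peaks, at 4.15 and 4.10 times away from promoters, and at 2.31 and 2.26 times at promoters.

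Of 28 consensus sequences, 12 had intervals above 1 in both libraries, 9 below 1 in both and 7 neither. The lowest mean ratios of both libraries were those of GATA (WGATAAGR, 0.505 and 0.304), LHX/DLX homeobox (YTAATTAR, 0.579 and 0.362), nuclear receptor class 3 (GNACANNNTGTNC, 0.483 and 0.537), the POU octamer (ATGCAAAT, 0.497 and 0.541) and ZNF143 (ACTACAANTCC, 0.349 and 0.745). The HNF1 sequence GTTAATNATTAAC was found in 0 footprints and 0 windows, so no ratio was formed. The AP-1 site TGASTCA stood at 1.02 and 0.847. Windows were kept outside footprints, so sites in footprints are missing from them, which raises those ratios that lie above 1. They were matched on width and peak but not on base composition, and a sequence preference of the cutting was not tested. The ratios alone therefore do not measure binding.

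**Figure D4:**
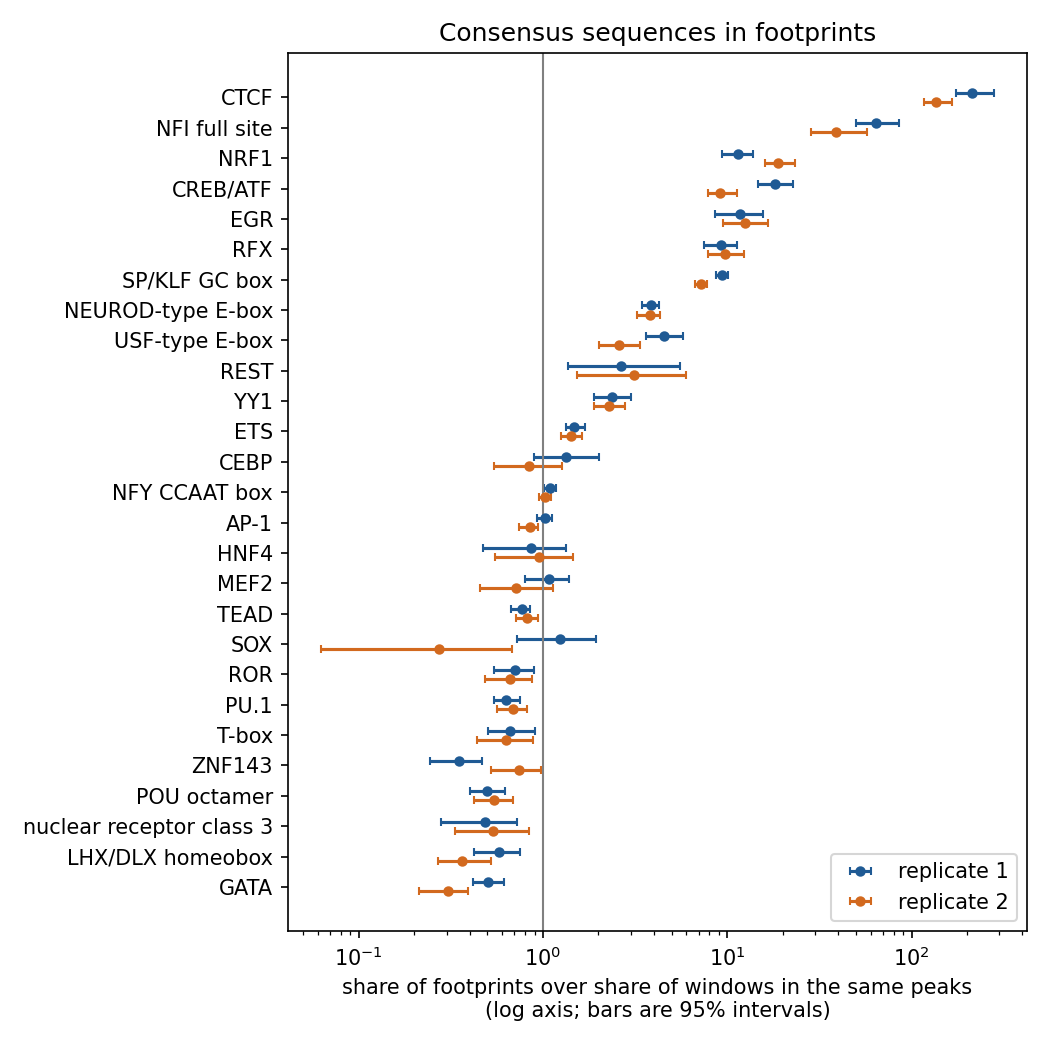
Ratio of the share of footprints holding each consensus sequence to the share of random windows in the same peaks, on a log axis, with 95% intervals from resampling peaks, in replicates 1 and 2. CTCF is highest at 214 and 136, and GATA, at 0.505 and 0.304, has the lowest mean of both libraries.

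Replicate 1 had 234094 footprints and replicate 2 had 154015, with a median width of 10 bp in each library. Within shared peaks, 32.2% of replicate 1 footprints and 39.8% of replicate 2 footprints matched one of the other library at 50% reciprocal overlap, 3.49 and 3.43 times the share after random placement in the same peaks (one-sided permutation p = 0.0099 for each, the smallest that 100 placements can give). Footprints lay within 500 bp of a TSS for 42.8% and 48.5%. Shared peaks held 2.85 and 2.28 footprints each, and peaks called in 1 library 1.09 and 0.587. Shared peaks were also stronger, with medians of 1.02 against 0.442 in replicate 1 and 0.815 against 0.429 in replicate 2. Strength was not matched in this comparison.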

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

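Alternatives for the spread with the stricter list, a higher percentile for lists and the dense windows were chosen after seeing the data. With the stricter list the mean number of peaks was 45021.5, the promoter share 40.9%, the Spearman rho of strength 0.929, the SD of the log2 ratio 0.38 and the number of lists above the 95th percentile for linked peaks 6 instead of 10. Fewer peaks by construction account for the first, and for the others the cause was not tested. Leaving out each replicate in turn gave 6 to 11 such lists, the lower value without replicate 1. With a promoter window of 1000 bp the promoter share was 37.7%, by construction. Footprints counted as shared at 1 bp gave 52.4% instead of 36.0%. The fold over chance stayed above 1 with the smallest p that 100 shifts can give, but its size ran from 40.6 with local shifts to 160 with reciprocal overlap. The X density stayed within 1 SD. The shared share ran from 55.4% with reciprocal overlap to 75.6% with the stricter list, and its SD, which depends on list length, does not measure stability. The number of lists with open promoters was 3 to 6 and that of consensus sequences above 1 was 11 to 13. With 2 libraries, the value of either alone always lies within 1 SD of their mean, so those comparisons say nothing about stability. Scaling by the median ratio moves no SD. For promoter shares of single lists, 10 percentiles under an alternative left the outer range and 8 entered it. For linked peaks 18 left and 10 entered, and for sequence ratios 9 and 4. None reversed. Among 99 named genes, 66 had a promoter peak in both libraries with the longer list and 50 with the stricter. The comparison over the union of peaks was not run, because no values are given for places without a peak, and the set of peaks called in both libraries is the main one for the spread. Sharing was lowest in the weakest decile, and whether depth limits it was not tested.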

Other observations

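The tests of depth, share of cuts, scaling, the crossing of GC content with strength, the dense windows and their thresholds were chosen only after the result was seen. Among biological explanations, only a different mix of brain cell types was tested for the patterns below. Both libraries belong to 1 group.

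Some regions were dense in peaks in only one library, and the genes there are named after their values were seen. In replicate 1 the densest 50 kb window was at Slc2a9 on chromosome 5 (38450001 to 38500000), with 44 peaks against 3 in replicate 2. Windows at Itpr2 (38 against 4), Lmntd1 (35 against 1), Cd46 (34 against 2) and Snap91 (34 against 0) followed. In replicate 2 the densest was at Ulk4 on chromosome 9, with 29 peaks against 2, followed by Zeb2, a forebrain transcription factor gene, with 22 against 2.

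Such windows numbered 68 in replicate 1 and 10 in replicate 2 and held 1272 and 175 peaks. The median strength in the windows was at most 0.842 times the 5th percentile elsewhere in the same library, and at least 56.4% of their peaks were weaker than that percentile in each library. By rules written after the result was seen, a calling threshold that was lower there was favoured over more accessible sites under one genome-wide threshold. The windows were picked for peaks that the other library lacks, and such peaks were weaker in general. Their median strength was 0.442 in replicate 1 and 0.429 in replicate 2, against 1.02 and 0.815 for shared peaks. Peaks in the windows were weaker still, with medians of 0.214 and 0.189, so this general weakness does not account for all of theirs. Unshared peaks in the windows overlapped FDR bases of the other library in 1.18% and 1.23% of cases, against 12.5% and 36.7% outside. Picking windows with few peaks of the other library itself lowers that share. The values cannot decide, because some peaks below that 5th percentile were also called outside the windows. Both explanations stay open, and the caller's background model is not given in the sources used here.

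Replicate 1 had 1.41 times as many peaks as replicate 2. The dense windows did not account for the difference, since the ratio was 1.40 without them. Deeper sequencing, one scaling factor, a larger share of cuts in accessible sites and GC content each may contribute and all stay open: the ratios of 1.59 in the strongest decile of shared regions, 1.18 between the 10th and 8th deciles, and 1.097 at the lowest GC content of the strongest decile do not bear on the extra peaks, because 99.6% of the strongest peaks were shared in each library. List length at one threshold also stays open, since the 74.4% of peaks shared at equal numbers decides nothing where equal numbers remove the difference itself. Depth, scaling and list length were first judged as argued against and the share of cuts as favoured, and all 4 judgements were changed to open after the results were seen, because the tests could not decide.

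The ratio of strengths between the libraries varied across shared regions. GC content may account for part of this, with a Spearman rho of 0.457 between GC content and the log2 ratio, and 0.340 on average within deciles of strength. Promoters stay open as a separate cause, since their excess of 0.30 (log2) over other regions shrank to 0.085 at matched GC content and strength, between the bounds set beforehand. A different mix of brain cell types was not detected as far as the lists reach, and it is not excluded. The 8 brain cell type lists lay between percentiles 11.17 (astrocyte) and 92.55 (oligodendrocyte) of regions matched on GC content and strength. Of these, 0 lay outside the outer percentiles set beforehand. Those lists held 14 to 53 regions, so smaller shifts were not detectable. That test did not cover the posterior and cerebellar list (percentile 1.69, 12 regions) or the forebrain list (2.89, 76 regions). Their percentiles were the lowest of the 18 lists, so picking them favours low values. Both were shifted the same way, with median log2 ratios of 0.022 and 0.176 against random means of 0.259 and 0.268. More forebrain and less posterior tissue in one library would move them in opposite directions, so these percentiles are no sign of it. A difference in the tissue taken was not tested and stays open.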
